A study of Mus musculus with 2 samples.

How the data were processed

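Droplet single-cell RNA sequencing was run on 2 libraries, 1 of mouse embryoid body (EB) cells and 1 of mouse yolk sac (YS) cells. Per the labels, EB cells were dissociated with Accutase at day 4 and yolk sac cells with collagenase, both were frozen and thawed, live cells were sorted, and suspensions of 300 cells per microlitre were loaded on the 10x Genomics Chromium system and sequenced on a HiSeq2500. The deposited values are raw UMI counts per gene and barcode, which the authors made against mm10. The aligner, the counting program, the annotation version and any read filter are not given in the sources used here. As deposited, each table lists 33456 genes and 737280 barcodes and was not filtered to cells. Of the gene identifiers 32655 are in GENCODE M21 (GRCm38), which gave the coordinates. The 71 symbols that several identifiers share were kept apart by identifier, and older symbols were matched for 2 marker genes.

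A barcode was kept as a cell when its UMIs reached 10% of the 99th percentile of the 3000 largest totals (6172 UMIs in EB, 6537 in YS), with at least 200 genes and at most 10% of UMIs from the mitochondrial genome. In EB 2020 barcodes passed the UMI minimum and 142 failed the mitochondrial limit, and in YS 801 passed and 26 failed. Scrublet (in scanpy 1.11.5) at a rate of 0.8% per 1000 cells marked 3 EB and 2 YS cells as doublets (0.16% and 0.258%, where 1.50% and 0.62% were expected), which were removed, so most doublets may remain. The 1875 EB cells held 50557130 UMIs (68.4% of the library) and ranged from 6233 to 99304 UMIs, and the 773 YS cells held 24074819 UMIs (79.5%) and ranged from 6557 to 114332. Empty droplets were taken as barcodes of rank 10001 to 50000 by UMI total, and the mean empty droplet held 0.988% of the UMIs of a median cell in EB and 0.191% in YS.

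Each library was clustered on its own: counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, seed 1). A cluster took the name of a marker list when at least 3 of its markers were 2-fold higher than in the library's other cells and seen in 25% of its cells, the mean log2 difference of the list was at least 0.5 (with 20 CPM added), and 2 markers of the list were among the 10 genes of highest fold. With 1 such marker the name was kept if no other list had one there, or if 2 of 3 of the list's markers were enriched. The marker lists were fixed before the data were examined, as were the settings for cells and clustering, the comparisons, the function lists, the rule for named genes and most of the alternatives. The naming rule was written after the clusters had been seen, and its last part was added later, to name the YS hematopoietic progenitor-like cluster. Without that part 18.0% of YS cells are unnamed in place of 3.62%. The names with "-like" are therefore descriptions, not identities measured otherwise.

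Between libraries, UMIs were summed over cells and scaled to a common total (CPM). Genes with at least 10 UMIs in both groups together were compared. With 1 library per group there are no replicates, so no test between groups was made and no p-value is given. The precision given is counting error: 95% exact Poisson, Clopper-Pearson and conditional binomial intervals. A gene with 0 UMIs in a group gives a bound against 3 counts, written as at least. This is a set floor and not a 95% limit, and it lies above the lower end of the 95% interval. A gene with 1 to 3 counts gives its ratio with the interval, where the plan had a bound below 3 counts. In list medians such genes stand at their bound. Each of the marker and function lists was placed among 10000 random lists matched over 20 bins of expression. The named genes were the 12 of largest ratio in each direction with at least 100 CPM and 30 UMIs in the higher group, leaving out unnamed gene models and mitochondrial genes, then the 2 highest and 2 lowest members of each list, and a fixed set of marker genes within each library. The text gives part of these, and 1 gene that met the rule is not reported here. Genes outside this rule (Prdm1 and Prdm14 in an EB cluster, Hbb-y in EB cells, and the genes that set the unnamed YS cluster apart) were chosen after their values were seen. Classes of at least 20 cells were compared across libraries. No class was shared, and the EB hemangiogenic progenitor-like and YS endothelial-like classes were compared in its place, a pair chosen after the classes were known. The random-list percentile and the intervals were tested on simulated data: among 15499 unchanged genes 95.9% of intervals held the true ratio, and among sets of 50 changed genes 94% to 98% did. The simulated counts were Poisson draws without variation between cells, which is what the intervals assume. The simulation therefore checked the calculation only, not how well the intervals cover the spread in these data.

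Alternatives covered the UMI minimum, mitochondrial limit, gene minimum, doublet removal, clustering settings, thinning to 6000 UMIs, a positive call at 2 UMIs, the scaling (TMM in edgeR 4.0.16, median of ratios in DESeq2 1.42.0, R 4.3.3), globin genes, gene filters, means over cells, erythroid cells and free RNA. Added after the data were seen were the names without the last part of the rule, removal of doublets at the expected rate, and the EB cluster with the highest hemangiogenic score alone. Raw reads were not analysed here. The YS stages were mixed before the library was made and cannot be separated by label.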

Results

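Single-cell transcriptomes were collected from 2 mouse sources of early blood and vessel cells, with 1 library each and therefore no replicates. The embryoid body (EB) library came from embryonic stem cells left to differentiate as floating aggregates for 4 days under conditions that favour hemangiogenic mesoderm, the mesoderm that gives rise to blood and endothelium. The yolk sac (YS) library came from a mixture of equal numbers of yolk sacs at the stages E9.5 and E10.5, from which about 70% of the Ter119-positive red cells, and the dead cells, had been sorted out. The EB library held 73915225 UMIs (unique molecular identifiers, each counting 1 captured transcript), and 1875 barcodes were kept as cells, with a median of 25537 UMIs and 4400 genes per cell. The YS library held 30294678 UMIs, and 773 cells were kept, with a median of 28461 UMIs and 4471 genes. Levels are CPM, UMIs summed over cells and scaled to a common total. Intervals are 95% intervals (exact Poisson for levels, exact Clopper-Pearson binomial for shares, exact conditional binomial for ratios), and they cover counting error only, not differences between cultures or litters. Key genes are given with their coordinates in mm10 (GRCm38).

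The first question was which cell states the day 4 EBs held. Streak and hemangiogenic states were the largest named classes. Primitive streak and nascent mesoderm-like cells were 361 of 1875 cells (19.3%, 17.5 to 21.1), and hemangiogenic progenitor-like cells, in 2 clusters, were 367 cells (19.6%, 17.8 to 21.4). Epiblast-like cells, which resemble the pluripotent layer of the embryo before gastrulation, were 10.4% (9.05 to 11.9), definitive endoderm-like cells 6.35% (5.29 to 7.55), allantois and extraembryonic mesoderm-like cells 6.08% (5.04 to 7.26) and naive pluripotent-like cells 4.69% (3.78 to 5.75). The remaining 4 clusters, with 33.7% of the cells, met no marker list well enough to be named. One of them (cluster 6, 162 cells) had 4 of 8 germ cell markers enriched, among them Prdm1 and Prdm14, and also the highest level of the streak gene T (488 CPM). Another (cluster 9, 104 cells) had 6 of 10 smooth muscle markers enriched, with Acta2, the smooth muscle actin, at 132 CPM. That cluster also had 5 of 12 epiblast and 3 of 9 definitive endoderm markers enriched, and 0 of 12 cardiac and lateral mesoderm markers. The names rest on these marker genes, so their levels in the clusters named by them are descriptions and not separate results.

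The larger of the hemangiogenic progenitor-like clusters (cluster 2, 276 cells, 14.7% of the library) and the smaller (cluster 10, 91 cells, 4.85%) differed in streak genes, hemangiogenic transcription factors and endothelial markers. Cluster 2 barely met its name, with 5 of 12 hemangiogenic markers enriched and a mean log2 difference of 0.54, where 0.5 was asked for. Its means for cardiac and lateral mesoderm and for allantois and extraembryonic mesoderm markers were both 0.41. In cluster 10, 9 of 12 hemangiogenic markers were enriched (mean 1.49). Cluster 10 had more Tal1 (118 CPM, 104 to 133, against 31.2, 27.3 to 35.5), Lmo2 (527 against 124), Gata2 (76.0 against 20.9) and Fli1 (76.0 against 2.05), transcription factors of the earliest blood and endothelial progenitors. Cluster 2 still had the streak genes Mixl1 (311 CPM against 40.4) and Eomes (237 against 34.7), and the receptor gene Pdgfra, which marks mesoderm with other fates, stood at 11.9 CPM against 3.33. Runx1, which is needed for definitive blood, was 29.9 CPM in cluster 10, 13.4 in cluster 2 and 34.1 in the allantois and extraembryonic mesoderm-like cluster. Of the 16 endothelial markers 7 were enriched in cluster 10 over the other EB cells and 0 in cluster 2, while Cdh5 (VE-cadherin) was 5.23 CPM (2.61 to 9.35) in cluster 10. Of the 12 hematopoietic progenitor markers 1 was enriched in cluster 10 and 0 in cluster 2. The embryonic globin genes Hbb-y, Hbb-bh1 and Hba-x had 0 UMIs in the EB cells, which allows up to 0.0593 CPM (3 counts of the total).

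The shares of some states depended on how cells were grouped. The hemangiogenic progenitor-like share was 5.13% with a UMI minimum of 20% of the 99th percentile, 4.64% at a clustering resolution of 0.6 and 5.12% with 1000 variable genes. With that minimum the epiblast-like share was 18.8% and the naive pluripotent-like share 2.44%, and at that resolution they were 0% and 14.9%, with 21.1% of cells allantois and extraembryonic mesoderm-like.

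**Figure D1:**
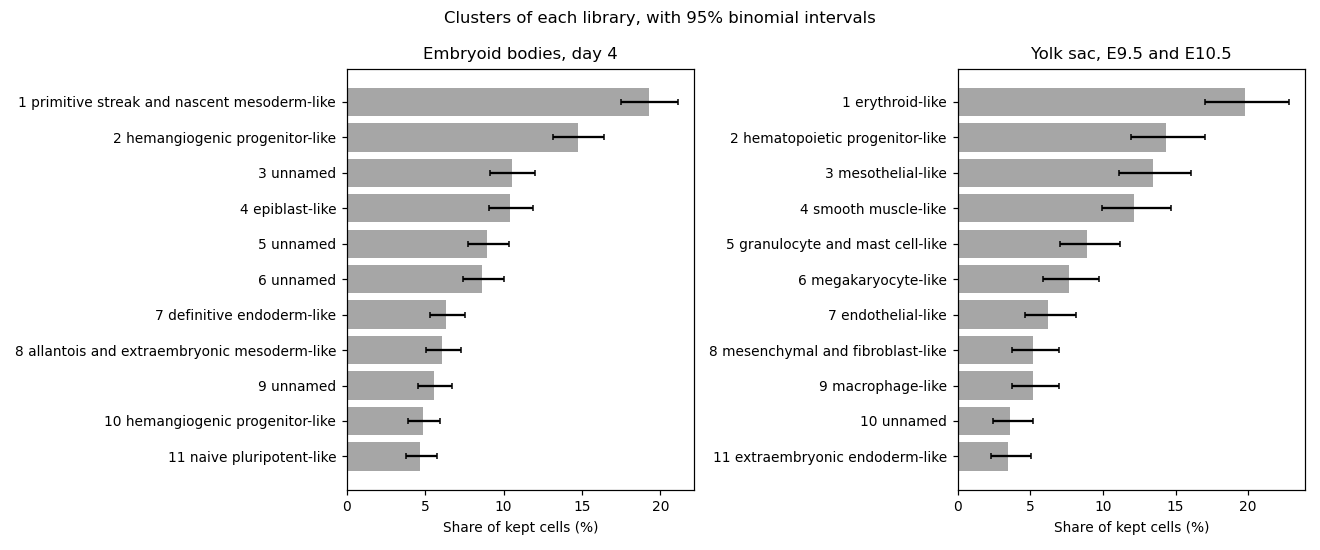
Share of the kept cells (percent, horizontal axis) in each cluster of the EB library (1875 cells) and of the YS library (773 cells); bars are shares and lines are 95% Clopper-Pearson intervals. Hemangiogenic progenitor-like cells fill 2 EB clusters (14.7% and 4.85%), and endothelial-like cells 1 YS cluster (6.21%).

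The next question was where Kdr and Etv2 were expressed in the EBs. Kdr encodes the VEGF receptor FLK1, which marks mesoderm able to form blood and endothelium (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458, minus strand, protein-coding). Etv2 encodes the ETS factor that commits mesoderm to these fates (ENSMUSG00000006311, chromosome 7, 30633616 to 30635852, minus strand, protein-coding). Kdr was highest in the hemangiogenic progenitor-like clusters, at 221 CPM (209.9 to 232) in cluster 2 and 229.5 (209.5 to 251) in cluster 10, against 68.9 in the primitive streak and nascent mesoderm-like cluster and 66.6 in the allantois and extraembryonic mesoderm-like cluster. Etv2 peaked in cluster 2, at 332 CPM (319 to 345), and was lower in cluster 10, at 200 (181 to 220.1), where Tal1 and Lmo2 were higher. Kdr and Etv2 were the 2 hemangiogenic markers among the 10 genes of highest fold in cluster 2. Their peaks there therefore partly restate its name. In pluripotent cells both were low: Kdr was 2.59 CPM in epiblast-like and 5.71 in naive pluripotent-like cells, and Etv2 was 22.7 and 9.66 CPM in the same order. Etv2 also stood at 85.3 CPM (74.2 to 97.6) in the definitive endoderm-like cluster, where 63.5% of its 211 UMIs came from 5 cells. Over the whole EB library Kdr was 65.9 CPM (63.7 to 68.2) and Etv2 112 CPM (109 to 115).

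At least 1 Kdr UMI was seen in 41.2% of EB cells (median depth 25537 UMIs) and at least 1 Etv2 UMI in 49.5%. The naive pluripotent-like cells, at a similar median depth of 25315.5 UMIs, had Kdr in 9.09% and Etv2 in 15.9%, and the epiblast-like cells, at 25019 UMIs, had Kdr in 5.13% and Etv2 in 24.6%. Free RNA at the level of the empty droplets would give a UMI in 1.39% of cells for Kdr and 2.95% for Etv2. In cluster 2 (median 25120.5 UMIs) the shares were 94.9% and 84.1%. The 2 genes were seen together in 30.1% of EB cells, and Etv2 was seen in 73.1% (69.8 to 76.2) of the 772 cells with Kdr and in 33% (30.2 to 35.9) of the 1103 cells without it. This pools clusters that differ in both genes. Within every cluster the share was higher with Kdr, but the gap varied, and in several clusters the intervals overlapped. It was 58.0% against 51.1% in cluster 8, and 76.9% against 23.6% in cluster 7. Kdr and Pdgfra were seen together in 14.1% of EB cells, in 36.3% of the primitive streak and nascent mesoderm-like cells, in 22.8% of cluster 2 and in 6.59% of cluster 10. These shares move with depth. With each cell thinned to 6000 UMIs, Kdr was seen in 23.3% of cells, Etv2 in 26.4% and both in 11.1%, and with at least 2 UMIs asked for, Etv2 was seen in 30.5% and both in 18.8%.

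**Figure D2:**
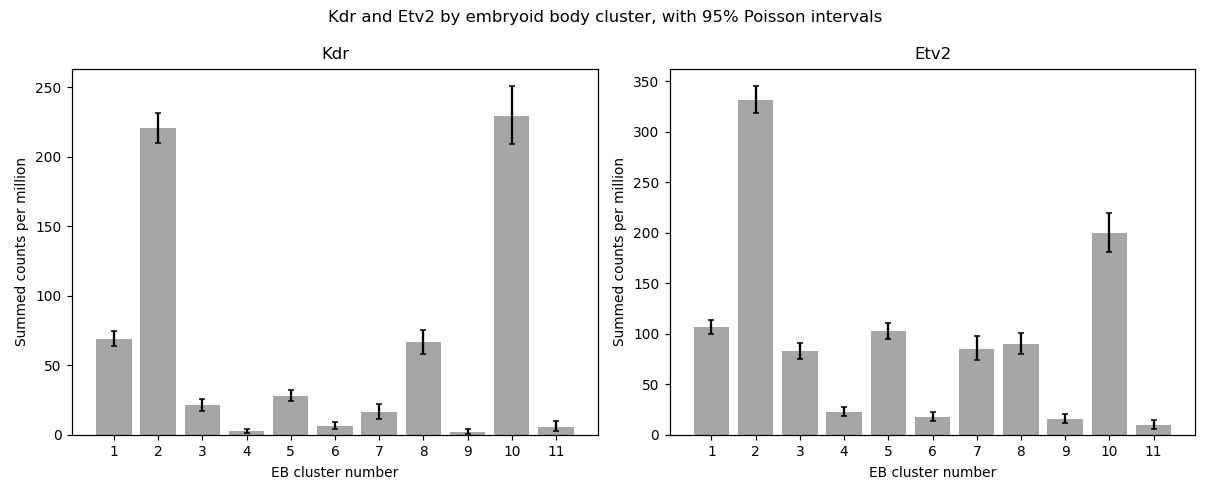
Summed level (CPM, vertical axis) of Kdr and Etv2 in each EB cluster; bars are levels and lines are 95% Poisson intervals. Kdr is highest in hemangiogenic progenitor-like clusters 10 and 2 (229.5 and 221 CPM), and Etv2 in cluster 2 (332 CPM). Both genes were among the markers that named cluster 2.

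In the yolk sac the question was which cell types the mixed E9.5 and E10.5 suspension held. Blood cells of several lineages stood beside the cells of the sac's wall. Erythroid-like cells were 153 of 773 cells (19.8%, 17.0 to 22.8) after the removal of most Ter119-positive cells, so this is not their share in the tissue. Hematopoietic progenitor-like cells were 14.4% (11.96 to 17.0), granulocyte and mast cell-like 8.93% (7.01 to 11.2), megakaryocyte-like 7.63% (5.86 to 9.74) and macrophage-like 5.18% (3.72 to 6.98). The granulocyte and mast cell-like name rests on 3 of 12 markers (Mpo, Prtn3 and Srgn), with a mean log2 difference of 0.76. That cluster also had 7 of 12 hematopoietic progenitor markers enriched (mean 0.62), so the name does not set it apart from progenitors. The wall was represented by mesothelial-like (13.5%, 11.1 to 16.1), smooth muscle-like (12.2%, 9.94 to 14.7), endothelial-like (6.21%, 4.61 to 8.15), mesenchymal and fibroblast-like (5.18%, 3.72 to 6.98) and extraembryonic endoderm-like cells (3.49%, 2.31 to 5.04). The mesothelial-like cluster had 7 of 12 mesothelial markers enriched (mean 1.21) but also 9 of 12 mesenchymal and fibroblast markers (mean 1.34). The mesenchymal and fibroblast-like cluster had 9 of 12 of its own markers enriched (mean 2.17) and 7 of 12 mesothelial markers (mean 1.32). These 2 names therefore do not separate distinct cell types. A cluster of 28 cells (3.62%) met no list.

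Globin levels set the erythroid-like cells apart, while the yolk sac's other blood clusters shared several marker genes. In erythroid-like cells the embryonic globins made up much of the RNA, with Hbb-y at 139118.9 CPM, Hbb-bh1 at 66039 and Hba-x at 58635, and the adult-type Hbb-bt and Hbb-bs at 1754 and 1129 CPM. The adult-type alpha globins were more abundant than these 2 adult-type beta globins. Over all YS cells Hba-a1 was 8264 CPM and Hba-a2 3015, against 13391 for Hba-x and 418 for Hbb-bt. In the other clusters Hbb-y lay between 155 CPM (mesothelial-like) and 246 CPM (endothelial-like). Runx1 was 109 CPM (99.4 to 119) in hematopoietic progenitor-like, 128 (115 to 143) in granulocyte and mast cell-like and 86.4 (71.2 to 104) in macrophage-like cells, against 10.8 (4.65 to 21.2) in endothelial-like cells. Myb, a factor of definitive progenitors, was 69.7 CPM in the megakaryocyte-like and 45.9 in the hematopoietic progenitor-like cluster. The megakaryocyte-like cluster was mixed: Pf4, a platelet chemokine, was seen in 27.1% of its cells, and Hbb-bh1 stood at 684 CPM, above the level of the other clusters that were not erythroid-like. Pf4 was higher in macrophage-like cells (281 CPM, 253 to 311) than in the megakaryocyte-like cluster (141, 127 to 157).

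Endothelial-like cells carried Lyve1 at 1379.6 CPM (1296 to 1467) and Stab2 at 479 CPM (431 to 532), which encode hyaluronan receptors of sinusoidal and lymphatic vessels, with Kdr at 514 CPM (464 to 568) and Cdh5 at 429 (384 to 479). Part of this program was also read in hematopoietic progenitor-like cells: Kdr was seen in 62.2% (52.5 to 71.2) of them, at a median depth of 40333 UMIs, against 1.31% of erythroid-like cells, at 33128 UMIs. Their Kdr was 34.3 CPM (29.0 to 40.1), Cdh5 15.2 (11.8 to 19.3) and Lyve1 24.6 (20.2 to 29.7), while Stab2 was 0.448 (0.0542 to 1.62). Etv2 in the yolk sac was 3.66 CPM (2.93 to 4.50) over all cells, 11.9 (8.89 to 15.5) in hematopoietic progenitor-like cells and 0 UMIs in endothelial-like cells, which allows up to 4.04 CPM. The mannose receptor gene Mrc1 was as high in endothelial-like cells (226 CPM, 193 to 263) as in macrophage-like cells (233, 207.5 to 261). Ttr (18609 CPM), Apoa1 (14101) and Afp (8428), serum protein genes of the yolk sac's endoderm, were at these levels in the extraembryonic endoderm-like cells.

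Hematopoietic progenitor-like cells were named by 1 leading marker, and the name was lost (0% of cells) with a UMI minimum of 20% of the 99th percentile, a mitochondrial share of up to 20%, or a resolution of 0.6, and without the part of the naming rule added last. The granulocyte and mast cell-like name was lost (0%) at a resolution of 0.6 and with a UMI minimum of 1000 or of 20% of the 99th percentile. With the last the endothelial-like share was 3.82%, and the extraembryonic endoderm-like share was 1.961% with a mitochondrial share of at most 5%.

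The main comparison between the libraries set all EB cells against all YS cells, to show how EB differentiation at day 4 stands beside the yolk sac. The EB cells were higher in genes of pluripotency and gastrulation, and the yolk sac was higher in genes of every blood lineage, of the vessel wall and of the visceral endoderm. Tdgf1, the NODAL co-receptor CRIPTO, was 652 CPM in EB cells against 2 UMIs in the yolk sac, a ratio of 7847 (2172 to 64799). Mesp1, a factor of nascent mesoderm, had a ratio of 5961 (1650 to 49222), the streak signal Fgf8 3327 (1138 to 16135), the pluripotency gene Dppa5a 2110.4 (1071 to 4889), the streak factor Eomes 1730.2 (479 to 14290) and Pou5f1 (OCT4) 1422 (773 to 2966). Mixl1 was at least 1478-fold higher in EB cells, with 0 UMIs in the yolk sac. Trh (ratio 1038.5), the WNT target Sp5 (486), T (481, 269 to 965), the retinoic acid hydroxylase gene Cyp26a1 (237, 159.5 to 371) and Upp1 (68.7, 57.6 to 82.6) completed the 12 genes with the highest ratios among well-measured genes.

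In the other direction the globin genes led. Hbb-y (31797 CPM in the yolk sac) was at least 535851-fold higher there, Hbb-bh1 at least 255429-fold, Hba-x at least 225672-fold, Hbb-bt at least 7041-fold and Hbb-bs at least 4455-fold, all with 0 UMIs in EB cells. Hba-a1 was 139272-fold higher (47656 to 675349) and Hba-a2 21773-fold (10567 to 54158). The copies Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are nearly identical in sequence, so the split between them is uncertain. Ttr was 29784-fold higher in the yolk sac (5345 to 1176499), the collagen gene Col3a1 18268-fold (3278 to 721626) and Afp 13507-fold (2423 to 533588), each with 1 UMI in EB cells. Lum, a matrix proteoglycan gene, was at least 9365-fold higher. Without its erythroid-like cells the yolk sac still had more of all 7 globin genes, with log2 ratios of EB over YS from -11.59 (Hbb-y) to -6.70 (Hba-a2). Empty YS droplets also held Hbb-y, at 15417 CPM of nuclear-genome UMIs. How much of the globin RNA in these remaining cells was free RNA was not measured for them together, so it does not show expression by them. Kdr was 2.65-fold higher in EB cells (2.43 to 2.89) and Etv2 30.6-fold (24.8 to 38.3).

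Among 15613 genes the median log2 ratio of EB over YS was -0.002, and levels correlated across genes with a Pearson r of 0.876 and a Spearman rho of 0.835. Genes are not independent replicates. Gene lists were compared by the median log2 ratio of their members and by its percentile among 10000 random lists of genes of like expression. All 12 primitive streak and nascent mesoderm markers were at least 2-fold higher in EB cells (median 8.80, percentile 100), as were all 12 epiblast markers (3.29, percentile 100), all 8 germ cell markers (3.73, percentile 100) and all 15 genes of WNT and FGF signaling in the streak (5.05, percentile 100). Of 11 naive pluripotent markers 8 were 2-fold higher in EB cells (3.97, percentile 100), while Klf2 was 3.56-fold higher in the yolk sac. Paraxial mesoderm markers (7 of 11 higher in EB cells, median 1.35, percentile 99.7), definitive endoderm markers (5 of 9, 1.13, percentile 99.9) and trophoblast markers (4 of 7, 1.75, percentile 99.8) also leaned to EB cells. So did BMP signaling (8 of 12, 1.57, percentile 100), with the BMP targets Msx2 (13.9-fold) and Msx1 (10.3-fold), and the de novo methylation and pluripotency chromatin genes (8 of 14, median 1.44, percentile 100), with Sall4 at 21.2-fold and L1td1 at 18.95-fold. Cardiac and lateral mesoderm markers were split (5 higher and 5 lower of 12, median 0.10, percentile 69.5), as were allantois and extraembryonic mesoderm markers (4 and 4 of 12, 0.53, percentile 99.3).

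Lists of the blood lineages were lower in EB cells throughout. The medians were -10.73 for 17 erythroid markers (16 at least 2-fold higher in the yolk sac), -5.91 for 12 hematopoietic progenitor markers (11), -6.36 for 10 megakaryocyte markers (all 10), -8.70 for 13 macrophage markers (all 13), -5.53 for 7 granulocyte and mast cell markers (all 7) and -2.95 for 4 adult blood leukocyte markers (all 4). Embryonic globins had a median of -17.96, adult globins -13.60, heme synthesis -2.46 (8 of 11 higher in the yolk sac) and complement and phagocyte genes -7.70 (13 of 14). Without the yolk sac's erythroid-like cells the medians were -6.13 for erythroid markers, -11.47 for embryonic globins, -8.01 for adult globins and -0.76 for heme synthesis. Vessel lists pointed the same way with 1 exception: endothelial markers had a median of -3.44 (13 of 16, percentile 0), venous and sinusoidal genes -2.46 (8 of 11), VEGF receptor and angiopoietin signaling -1.19 (7 of 12, percentile 0.38), hemangiogenic progenitor markers -1.70 (9 of 12, percentile 0) and the Etv2 and hemangiogenic transcription factors -2.67 (15 of 19, percentile 0), while arterial genes had a median of 1.04 (6 of 11 higher in EB cells, percentile 98.9). Among the arterial genes Cxcr4 was 27.0-fold and Hey1 8.04-fold higher in EB cells, and the Notch ligand gene Dll4 19.7-fold higher in the yolk sac. As a mean over cells in place of a sum, the arterial median was 0.25.

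The yolk sac was also higher in extraembryonic endoderm markers (median -8.48, 11 of 12), lipoproteins and serum proteins (-8.94, 11 of 12), mesenchymal and fibroblast markers (-3.92, 8 of 12), basement membrane and matrix genes, collagens among them (-1.85, 11 of 14) and Hox genes (-2.16, 21 of 31), with Hoxc8 at 486-fold, whereas Hoxb1 was 21.2-fold and Hoxd9 13.0-fold higher in EB cells. Smooth muscle markers (-0.90, percentile 0.44) and contractile genes (-0.87, percentile 0.18) had 5 of 10 members each higher in the yolk sac, while mesothelial (-0.29, percentile 16.0) and neuroectoderm markers (-0.48, percentile 25.2) were within the range of random lists. Glycolysis genes were higher in EB cells (median 0.90, percentile 100), with 5 of 15 at least 2-fold higher, among them the glucose transporter gene Slc2a3 (2.48-fold) and the lactate transporter gene Slc16a3 (2.44-fold), while Hk1 was 9.88-fold higher in the yolk sac. Hypoxia response genes (-0.33, percentile 10.9), oxidative phosphorylation (-0.07, percentile 19.4), S phase (-0.04, percentile 44.9) and G2 and M phase genes (-0.08, percentile 27.8) stood near 0. Cytoplasmic ribosomal protein genes (0.35, percentile 100) and genes of the mitochondrial genome (0.34, percentile 95.3) were slightly higher in EB cells. Imprinted genes went both ways (7 of 18 higher in the yolk sac and 5 in EB cells, median -0.28, percentile 2.66). Immediate early and heat shock genes, which respond to cell handling and were measured here after different dissociations, were higher in the yolk sac (12 of 17, median -1.98, percentile 0), with Hspa1a at 1188 CPM against 3.74, a 318-fold difference (275 to 369).

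**Figure D3:**
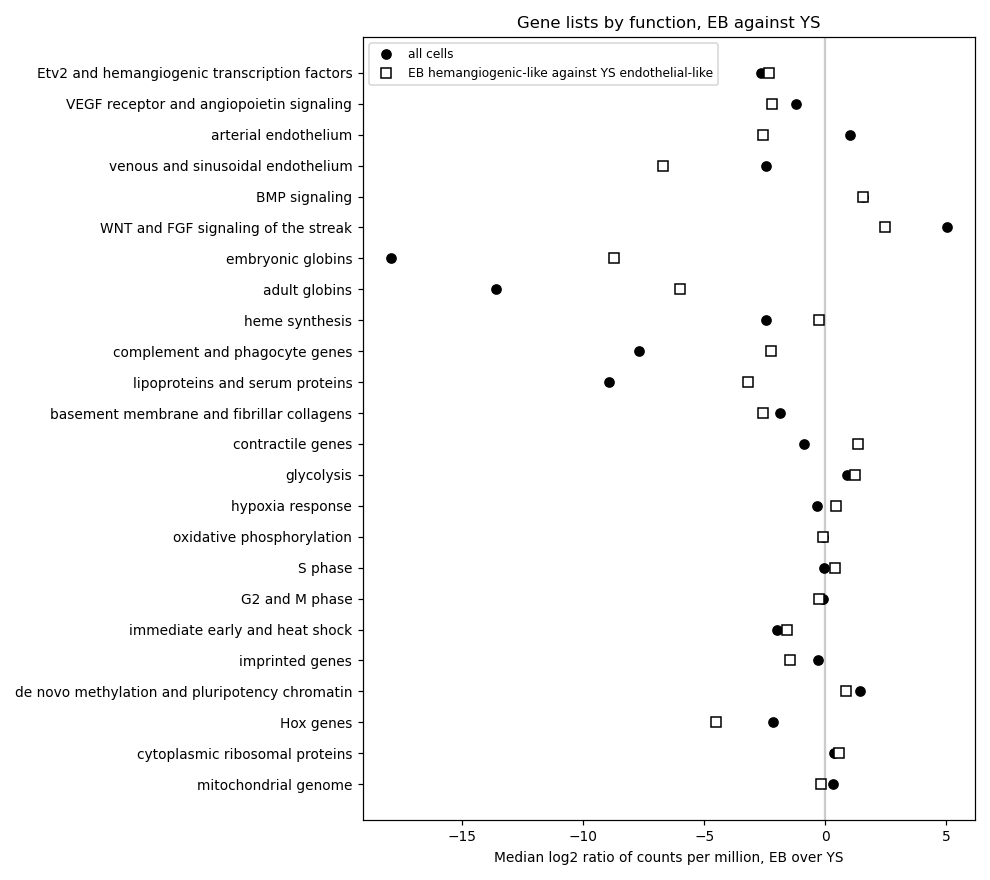
Median log2 ratio of EB over YS (horizontal axis) for each function list; filled circles are all cells, and open squares are EB hemangiogenic progenitor-like against YS endothelial-like cells. WNT and FGF signaling lies on the EB side in both (5.05 and 2.49), and venous and sinusoidal genes on the YS side in both (-2.46 and -6.72).

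No class name was held by both libraries, so a pair of classes with blood or vessel genes was compared: the 367 hemangiogenic progenitor-like EB cells (9417446 UMIs) with the 48 endothelial-like YS cells (742994 UMIs). The EB cells were higher in streak genes, and the YS cells in venous and sinusoidal vessel genes. Etv2 and the endothelial markers were among the genes by which these classes were named, so their direction here follows from the naming. Etv2 was 302 CPM in the EB cells and at least 74.9-fold higher than in the YS cells, where it had 0 UMIs. Phlda2, an imprinted growth regulator, had a ratio of 404 (138 to 1960.4), the epithelial keratin gene Krt8 269.8 (48.4 to 10661), the heparan sulfate proteoglycan gene Gpc3 175.5 (31.5 to 6934), Cyp26a1 81.4 (27.8 to 395) and Pou5f1 43.2 (14.8 to 209.7). Krt8 and Gpc3 had 1 UMI each in the YS cells, so their ratios cannot be ranked against the bounds that follow. Tdgf1 was at least 121-fold higher, Dppa5a at least 65.5-fold, Mixl1 at least 62.1-fold, Mesp1 at least 56.0-fold, Eomes at least 47.6-fold and Fgf3 at least 43-fold. In EB cluster 10 alone the ratio was 117 for Phlda2 (39.9 to 568) and 108 for Gpc3 (19.2 to 4267), and the bounds were at least 49.5-fold for Etv2, 80.8-fold for Dppa5a, 78.4-fold for Fgf3, 10-fold for Mixl1, 9.65-fold for Tdgf1, 8.59-fold for Eomes and 4.94-fold for Mesp1.

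The YS endothelial-like cells had 6496-fold more Lyve1 (1794 to 53711), 2282-fold more Igfbp7 (404 to 90609), 1191-fold more of the protocadherin gene Pcdh17 (325 to 9910.3) and 932-fold more Gimap4 (360 to 3442). In the EB cells Igfbp7 had 1 UMI, and Lyve1 and Pcdh17 had 2 each. Genes with 0 UMIs in the EB cells were Gpr182 (at least 1969-fold higher in the yolk sac), the endothelial lectin gene Clec14a (at least 1622-fold), Stab2 (at least 1504-fold), Stab1 (at least 731-fold), the caveola gene Sdpr (at least 934-fold), the vessel sialomucin gene Emcn (at least 870.3-fold) and Xist, the RNA that silences an X chromosome in female cells (at least 938-fold). Hbb-y (at least 773-fold) met the same rule, at 246 CPM in the YS cells against 139118.9 in erythroid-like cells. All 16 endothelial markers, which named the YS class, were at least 2-fold higher in it (median -6.56), with Plvap at 343.5-fold, Tie1 at 184-fold and Tek at 165-fold, and at the low end Sox17 at 5.66-fold and Egfl7 at 4.31-fold. Against EB cluster 10 alone Plvap was 166-fold, Tie1 41.1-fold, Tek 36.8-fold, Sox17 1.85-fold and Egfl7 1.59-fold higher in the YS cells. All 11 venous and sinusoidal genes (median -6.72), 10 of 11 genes of VEGF receptor and angiopoietin signaling (-2.20, percentile 0), 7 of 11 arterial genes (-2.55) and 9 of 13 basement membrane and matrix genes (-2.56) were also higher in the YS cells. Hox genes (13 of 16, median -4.53), imprinted genes (12 of 18, -1.47, percentile 0.03) and immediate early and heat shock genes (12 of 16, -1.58, percentile 0.06) lay on the same side.

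On the EB side stood the streak and nascent mesoderm markers (10 of 12, median 3.85), the allantois and extraembryonic mesoderm markers (7 of 9, 5.33), epiblast markers (6 of 12, 1.20), BMP signaling (8 of 12, 1.58), WNT and FGF signaling (10 of 14, 2.49) and glycolysis (9 of 15, 1.22), all at percentile 100. Tal1 was 3.41-fold higher in the EB cells (1.89 to 6.89) and 7.96-fold higher in EB cluster 10 alone. In cluster 10 alone the medians were 2.70 for streak, 3.305 for allantois and 2.435 for epiblast markers. They were 0.92 for BMP signaling, 1.87 for WNT and FGF signaling, 1.15 for glycolysis and -4.56 for venous and sinusoidal genes. Oxidative phosphorylation genes were within 2-fold in 16 of 16 cases (median -0.10). Hemangiogenic progenitor markers (7 of 11 higher in the YS cells and 3 in the EB cells, median -1.32, percentile 0.615) and the Etv2 and hemangiogenic transcription factors (9 and 3 of 14, -2.31, percentile 0) had lower medians in the EB cells. In EB cluster 10 alone, which was taken for its high score on the hemangiogenic markers, these medians were -0.48 and -0.55, as that choice would favour. Their percentiles there were 19.7 and 18.4, within the range of random lists. Some processing alternatives, listed below, gave similar medians. In them the class was still named by the same markers, and its share of EB cells was near that of cluster 10. They are therefore not independent of that choice. The lower medians depend on the grouping. The endothelial markers had a median of -4.72 in cluster 10 alone (14 of 16 higher in the YS cells).

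The median log2 ratio over all 11639 genes of this comparison was -0.36 (0.006 with TMM factors), and 2358 genes had fewer than 3 counts in the small YS class and stand at that bound. The bound is 4.04 CPM in the YS class and 0.319 CPM in the EB class. A gene with less than 4.04 CPM in EB and 0 UMIs in YS therefore stands as higher in YS. List medians and counts lean to YS for this reason. Germ cell markers summed to 13.4 CPM in EB and 4.04 in YS, yet 2 of 5 stood at least 2-fold higher in YS. With TMM factors or median-of-ratios factors the oxidative phosphorylation median was 0.27 or 0.24.

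The last comparison asked which YS cluster each EB cluster resembled most, by correlation of log2 levels across 11029 genes. All 11 EB clusters were nearest to the unnamed YS cluster of 28 cells, with Pearson r from 0.817 (naive pluripotent-like) to 0.866 (allantois and extraembryonic mesoderm-like). That YS cluster was set apart from other yolk sac cells by Id2, Crabp2, Sox11 and Meox1. The Tal1 and Lmo2-rich EB cluster 10 had r = 0.846 with it, 0.841 with hematopoietic progenitor-like, 0.829 with mesothelial-like and 0.786 with endothelial-like YS cells. With the 2000 most variable genes these values were 0.525, 0.325, 0.420 and 0.429, so the order of the others changed and the nearest cluster did not. EB cluster 2 had r = 0.859 with the unnamed cluster and 0.759 with the endothelial-like cells. The 28 cells carried another name in 5 planned or added settings, doublets kept among them, and the match was not repeated there.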

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

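Of the tests reported here, the one on free RNA was chosen only after its result was seen. The barcodes left out as cells for having too few UMIs carried a signal in data no comparison used. In EB these were 1591 barcodes with at least 1000 UMIs but fewer than the minimum of 6172, and their median mitochondrial share was 23.7%; in YS they were 516 barcodes with a median share of 43.1%. Genes were compared as CPM of nuclear-genome UMIs, left-out barcodes over kept cells.

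In EB, Kdr was 3.98-fold higher in left-out barcodes than in kept cells (3.69 to 4.28), Pdgfra 6.60-fold (5.76 to 7.54) and Runx1 3.49-fold (2.73 to 4.42), while Etv2 was at 0.991-fold (0.893 to 1.10). In YS, Stab2 was 11.4-fold higher (9.24 to 13.9), Cdh5 6.94-fold (5.47 to 8.74), Kdr 5.96-fold (4.85 to 7.28), Lyve1 4.80-fold (4.11 to 5.59) and Pecam1 3.20-fold (2.31 to 4.34). Pf4 was 5.31-fold higher, Mrc1 3.75-fold, Col1a1 3.90-fold, Ttr 2.65-fold, Afp 2.61-fold and Apoa1 2.53-fold, whereas Hbb-y was at 0.459-fold.

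For Kdr in EB, free RNA as the source is argued against by the empty droplets, with 56.5 CPM against 270 (253 to 288) in left-out barcodes. More hemangiogenic cells among the damaged ones is argued against as the main source: summed hemangiogenic transcription factors exceeded other classes' factors by 0.18 on the log2 scale (0.07 to 0.28), against 1.99 (1.89 to 2.10) for Kdr. By gene, the median log2 ratio was 0.37 for 10 hemangiogenic factors and 0.05 for 19 other factors. A smaller rise in such cells is not excluded, and Cdh5 (4.72-fold, 1.83 to 10.9) and Pecam1 (4.64-fold, 2.61 to 7.91) were also higher, at few UMIs. A candidate explanation is that damaged cells kept RNA bound to membranes: 30 of 30 genes for membrane or secreted proteins of other classes were also higher, with a median log2 ratio of 1.71 (quartiles 1.10 and 2.17). It does not cover Runx1, a transcription factor gene. No biological explanation of the groups was tested, and the loss of vessel cells from the kept YS set was not tested either.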

How the results depend on the processing

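The values for the naming rule, for doublets at the expected rate and for the Tal1 and Lmo2 cluster alone were chosen after the data were seen. Of 2560 values recomputed under 25 alternatives, 2279 stayed within their interval or within 1.5-fold, 281 moved and 0 reversed, where a reversal is a changed sign of a named gene or of a list outside the random range; some list medians inside that range changed sign, such as oxidative phosphorylation in hemangiogenic against endothelial cells (-0.10, and 0.27 with TMM). The moves were uneven: 51 of 83 values at resolution 0.6, 46 of 83 with 1000 variable genes and 41 of 65 with the Tal1 and Lmo2 cluster alone. With TMM 0 of 139 values moved. Shares and cell counts could not reverse under this definition, and the genes named first were picked for large ratios. Few reversals were therefore possible from the start. Cells kept ranged from 1677 to 2015 in EB and 654 to 876 in YS. For each moved value the cause was not tested, except where the setting itself lowers detection. The EB hemangiogenic progenitor-like share was 5.13% with a minimum of 20% of the 99th percentile, 4.64% at resolution 0.6, 5.12% with 1000 variable genes, 17.5% with up to 20% mitochondrial UMIs and 17.1% with 15 principal components. The YS endothelial-like share was 3.82% with the minimum of 20%. The YS hematopoietic progenitor-like share was 20.9% with a minimum of 1000 UMIs, and 0% with the minimum of 20%, up to 20% mitochondrial UMIs, resolution 0.6 or the shorter naming rule. Cells with Kdr were 23.3% after thinning to 6000 UMIs and 31.2% at 2 UMIs, cells with Etv2 26.4%, 30.5% and, with a minimum of 1000 UMIs, 47.1%, and cells with both 11.1% and 18.8%; fewer counts lower each. In all cells, the endothelial median was -2.83 with the minimum of 20% and -4.38 as a mean over cells, which gave VEGF signaling -1.80. For hemangiogenic against endothelial cells, the minimum of 20%, resolution 0.6, 1000 variable genes and the Tal1 and Lmo2 cluster alone gave, in that order, -0.65, -0.54, -0.64 and -0.55 for hemangiogenic transcription factors, -4.69, -4.67, -4.83 and -4.72 for endothelial markers and -0.44, -0.50, -0.54 and -0.48 for hemangiogenic markers. VEGF signaling was -2.80 with 1000 variable genes. No paired analysis was possible because the 2 libraries come from different sources with 1 sample each. Depth limits small classes: in the YS endothelial-like class, with 742994 UMIs, a count of 0 allows up to 4.04 CPM (3 counts).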

Other observations

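All tests reported in this part were chosen after the results were seen. Imprinted genes, which are expressed from the maternal or the paternal copy, went both ways: of 18 measured, 7 were at least 2-fold higher in the yolk sac, 5 in EB cells and 6 were within 2-fold. H19 was 329-fold higher in the yolk sac (271 to 403) and the zinc finger gene Plagl1 44.1-fold higher, while Phlda2 was 18.2-fold and Impact 5.16-fold higher in EB cells.

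Among the other lists, single genes differed between all clusters of EB and all clusters of YS. Of 80 ribosomal protein genes 77 were within 2-fold between the libraries, but Rpl29 was 51.2-fold higher in the yolk sac (48.9 to 53.7), at 1814 CPM against 35.4. It lay between 29.0 and 38.7 CPM in the EB clusters and between 1102 and 2093 in the YS clusters. The heat shock gene Hspa1a was 0.808 to 4.55 CPM in the EB clusters and 126 to 1899 in the YS clusters, lowest in extraembryonic endoderm-like cells. No explanation of either was tested. Without reads it is not known whether the low Rpl29 count in EB reflects expression or how reads were assigned to the gene.

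Etv2 in the EB definitive endoderm-like cluster was 85.3 CPM (74.2 to 97.6), with 63.5% of its UMIs in 5 cells. Free RNA as its source is argued against, since the empty droplet profile adds 1.44 CPM to the cluster. Doublets with hemangiogenic cells cannot be told apart from expression in endoderm-like cells. Kdr in the cluster was at most 22.0 CPM, below the 62.8 CPM that average hemangiogenic cells would bring, but 33 of 94 hemangiogenic cells rich in Etv2 (35.1%) had a Kdr to Etv2 ratio as low as the cluster's.

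Embryonic globins in the YS megakaryocyte-like cluster had a ratio of Hbb-bh1 to Hbb-y of 2.81 (2.56 to 3.09), against 0.475 in erythroid-like cells. Free RNA as their source is argued against by the ratio of 0.552 in empty droplets. Doublets with erythroid cells cannot be told apart for part of the cells: 6 of the 14 cells rich in Hbb-bh1 had a ratio above that of every erythroid-like cell (highest 6.01), and the others did not. The values are consistent with early erythroid cells within the cluster: the cells rich in Hbb-bh1 had Pf4 at 2.76 CPM (0.334 to 9.96), against 198 (178 to 220.1) in the cluster's other cells. They also had more Klf1 (207 CPM against 141) and Epor (95.1 against 49.7), erythroid genes.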
